A study of Mus musculus with 59 samples.

How the data were processed

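Bulk RNA was measured by RNA sequencing in whole pancreatic tumours of mice and in cells cultured from such tumours. The gene table holds estimated counts per gene and library, which the authors made with kallisto, a pseudoaligner, against mm10, per the submitters' processing notes; the versions are not given in the sources used here. Per the labels' protocols, RNA was extracted with RNeasy columns, kept where its integrity number exceeded 8, and made into libraries with the Illumina Stranded mRNA kit. The deposited expected counts are not all whole numbers (71.8% of the values are), so they were rounded to whole numbers before any test. The table has 46517 genes by Ensembl identifier, of which 26650 had a count in at least 1 library. Ignoring the version suffix, 46005 identifiers matched the GENCODE vM21 annotation of the same build (27555 with the suffix), which gave symbols and coordinates. The other 512 identifiers held between 0.0683% and 0.176% of a library's counts and stayed in as unnamed genes. All 59 columns of the table matched a library's title, and 0 were left unmatched.

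Groups came from the titles and genotype labels alone: tissue or medium (bulk tumour, complete medium, dropout medium), floxed gene (KTrp53 or KPten) and cell of origin (acinar with Ptf1aCreER, ductal with Sox9CreER). Within groups, 323 pairs of libraries were compared by the ratio of the squared difference of their counts to that expected from counting alone, over genes with at least 50 counts in the pair. In 2 pairs the median ratio was below 1.5: ductal-derived KTrp53 cultures 14 and 15 (0.587) and acinar-derived KTrp53 cultures 13 and 14 (1.04), all in complete medium. Their mean chi-square, which counting alone puts at 1, was 2.48 and 2.00, so some genes differed by more than the sampling noise. The counts of each pair were summed and counted as 1 sample, which leaves 57 libraries, 48 of them cultured. The next lowest ratio was 3.41 and the median over all pairs 64.3. In complete medium, acinar-derived KTrp53 cultures 3 and 4 (3.41) and 12 and 13 (5.58), ductal-derived KTrp53 2 and 5 (6.92) and acinar-derived KPten 1 and 3 (4.83) were thus also close. They were counted as separate samples, and if such pairs share a tumour the p-values are too small. Library totals ran from 17.1 to 58.4 M counts (M for mega). Per the series design, each tumour was divided for bulk sequencing and culture, and the labels do not say which libraries share a tumour. The p-values treat bulk tumours and cultures as independent samples and measure the spread between libraries.

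Every gene was tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, genes kept by filterByExpr with a minimum count of 10, robust quasi-likelihood fits and 2-sided quasi-likelihood F tests. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Bulk tumours were fitted alone (15816 genes), all cultures together in 8 groups (16567 genes), and bulk tumours with the complete-medium KTrp53 cultures for the comparisons between tissue and culture (16978 genes). Genotype, medium and tissue effects were averaged over both origins with equal weight. Log2 fold changes are given with their standard error (SE), and counts per M counts (CPM) with their standard deviation (SD) after TMM scaling. A fold change against a group with no counts in any of its libraries is given as a lower bound, from 3 counts over that group; such bounds, like the p-values of single genes, cannot see errors in library preparation.

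In all, 32 gene lists, with 591 of 594 genes in the table, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01. The tests were repeated with an estimated correlation and with fry, which asks only whether the genes of a list move one way. The lists cover acinar, duct, islet, mesothelial, tuft, fibroblast, endothelial, red blood and immune cell markers, PDAC subtype genes, epithelial and mesenchymal genes, signalling and metabolic targets, mitochondrial and sex-linked genes and early stress genes. List members were counted both over all genes and adjusted over the list alone. Genes named in the text are, per comparison, the 6 highest and 6 lowest fold changes among called genes with an average log2 CPM of at least 2, leaving out predicted genes, or the called genes and then the smallest p where fewer than 12 were called. To these come the 2 to 4 members with the smallest p in each list described, and Trp53, Pten, Kras, Sox9 and Ptf1a. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

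Chosen after the data were seen were a search for library batches, a fit on protein-coding genes only, a fit with the near-identical libraries kept apart, a fit with Ddx3y class (above or below 20 CPM) as a term, and the comparison of origin effects between genotypes in dropout medium. Batches were sought because complete-medium KTrp53 libraries differed in processed pseudogenes, copies of messenger RNAs whose counts depend on how reads are assigned. Clustering on 208 of them (at least 2 CPM, pseudocount 0.5) was cut into 3 groups, called batches, a number that was set and not found. Values of pseudogenes describe these batches and are no separate test of them. The labels do not say what sets the batches apart. Batch A held 6 ductal-derived and 2 acinar-derived libraries, batch B held 4 and 8, and batch C held 4 and 9. Gm12715 lay at 108 to 500 CPM in batch C and at most 7.43 CPM in the others, and Rpl39-ps at 129 to 165 CPM in batch A and at most 30.3 CPM in the others. Batch and origin could therefore be separated within these cultures. In complete medium Rpl39-ps lay at 57.0 to 71.6 CPM in KPten cultures, outside the range of every KTrp53 batch. By this pseudogene, genotype there and medium in KPten coincide with a separate library set, and preparation may add to those differences. In dropout medium Rpl39-ps lay at 1.66 to 6.02 CPM in KPten and 3.12 to 6.19 CPM in KTrp53 cultures, and Gm12715 at most at 2.90 CPM, so these markers did not set the genotypes apart, and both KTrp53 ranges overlapped those of batch B. For tissue, 10647 to 12379 genes were called against the cultures of any 1 batch.

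Replicate numbers recur across groups, so a fit with the number as a block was made for each comparison. Numbers were taken to pair libraries where the correlation of their deviations from the group means was above 0.1 in every one of 3 or more pairs. Only acinar-derived KPten cultures in complete and dropout medium met this, with correlations of 0.168 to 0.309 over 3 pairs, each library correlating best with its own number. The 2 ductal-derived KPten pairs gave 0.131 and 0.181, each library also correlating best with its own number, but were too few to meet the rule. There the Y-linked Ddx3y lay at most at 0.200 CPM in complete and at 77.7 CPM or more in dropout medium, so shared animals would need loss of the Y chromosome in complete medium. The pairing comes from the data and shared numbers only, and the labels give the paired acinar-derived cultures different numbers of floxed Pten alleles. Other alternatives were RLE scaling, no count filter, a stricter filter (1 CPM in 25% of libraries), fits without robust estimation, DESeq2 1.42.0, fits on only the groups compared, leaving out each library in groups of 5 or fewer, and leaving out libraries labelled with 1 floxed allele.

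Each fit was tested on simulated data drawn from the real means and library sizes with 100 genes changed 2-fold and 100 changed 4-fold. For a 4-fold change the fits recovered 68 of 100 genes in the bulk origin comparison, 98 in complete-medium KTrp53, 71 in complete-medium KPten, and 56 and 63 in dropout KTrp53 and KPten. They recovered 92 and 72 for genotype in complete and dropout medium, 86 and 81 for medium in KTrp53 and KPten, 92 for tissue, and 61 and 62 for the interactions of origin with genotype and with tissue. For a 2-fold change recovery ran from 14 of 100 genes (origin, dropout KPten) to 77 of 100 (origin, complete KTrp53), and false calls were at most 7.07% of calls. The changed genes were drawn only from those above a minimum mean CPM. Counts were drawn independently, without batches, sex differences, shared animals or correlation between genes. These rates therefore hold for such simulated data and may not carry over to the real libraries. Genes that share long stretches of sequence with copies elsewhere, such as Tpm3-rs7, Eno1b, Rps12, Rps12l1, Rps27rt, Vcp-rs, Hist1h2ap, Idi2 and the Amy2a genes, are uncertain, because reads can be split between copies.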

Results

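Pancreatic ductal adenocarcinomas (PDAC) were induced in mice by switching on oncogenic Kras and deleting floxed Trp53 (KTrp53) or Pten (KPten) with a CreER recombinase. The recombinase was expressed from Ptf1a, a transcription factor gene of acinar cells, which secrete digestive enzymes, or from Sox9, a transcription factor gene of duct cells. Tumours are called acinar-derived or ductal-derived accordingly, and the series asks how the cell of origin shapes the tumour transcriptome. RNA was sequenced from 9 bulk KTrp53 tumours (5 ductal-derived, 4 acinar-derived) and from cultured cells. In complete medium there were 15 ductal-derived and 20 acinar-derived KTrp53 libraries and 3 and 3 KPten libraries. In dropout medium there were 2 and 2 KTrp53 and 2 and 3 KPten libraries. What the dropout medium lacks is not given in the sources used here. Bulk libraries held 24.4 to 33.9 M counts (M for mega), complete-medium libraries 17.1 to 58.4 M and dropout libraries 19.7 to 29.5 M. Among the complete-medium KTrp53 cultures, ductal-derived 14 and 15 and acinar-derived 13 and 14 had median squared differences of 0.587 and 1.04 times those expected from counting alone. Each pair was counted as 1 sample, so these groups have n = 14 and n = 19. Other libraries were also closer than most and may share a tumour, which the labels do not say.

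The targeted genes were examined first. Trp53 (ENSMUSG00000059552.12, chromosome 11, 69580359 to 69591873 on mm10) lay at 5.19 ± 0.99 CPM (SD, n = 14) in ductal-derived and 17.9 ± 29.8 CPM (n = 19) in acinar-derived complete-medium KTrp53 cultures, against 127 ± 14.5 (n = 3) and 99.2 ± 17.6 CPM (n = 3) in the KPten cultures. The 1 KTrp53 culture labelled with a single floxed Trp53 allele, acinar-derived 8, held 135 CPM, and the others labelled with both alleles floxed held 3.37 to 39.6 CPM. Bulk KTrp53 tumours held 31.9 ± 8.71 (n = 5) and 26.3 ± 7.39 CPM (n = 4). Pten (ENSMUSG00000013663.7, chromosome 19, 32757497 to 32826160) was lower in complete-medium KPten than KTrp53 cultures by a log2 fold change of -0.84 ± 0.16 (SE, adjusted p = 0.00011), and remained between 49.0 and 93.3 CPM there. In dropout medium the Pten difference was -0.24 ± 0.23 (adjusted p = 0.50), and ductal-derived KPten culture 2, labelled with 1 floxed allele, held 188 CPM against 72.4 to 96.0 CPM in the other 4. Pten RNA therefore did not separate the KPten labels from the KTrp53 labels in every library. Kras (ENSMUSG00000030265.13, chromosome 6, 145216699 to 145250239) was detected in every group, at group means of 62.8 to 258 CPM. Ptf1a was not detected at this depth in any cultured library and lay at 2.22 ± 3.26 CPM (n = 5) in ductal-derived bulk tumours.

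Sox9 (ENSMUSG00000000567.5, chromosome 11, 112782224 to 112787760), the gene that drives the recombinase in the ductal model, separated the origins in culture. All 21 ductal-derived cultures held 45.5 to 545 CPM and all 27 acinar-derived cultures 2.93 to 36.8 CPM. The log2 difference was 3.69 ± 0.34 (adjusted p = 1.4e-10) in complete-medium KTrp53, 4.39 ± 0.85 (adjusted p = 0.011) in complete-medium KPten, 3.12 ± 0.84 (adjusted p = 0.0093) in dropout KPten and 3.54 ± 0.99 in dropout KTrp53, where it narrowly missed the threshold (adjusted p = 0.051). Bulk tumours held 308 ± 67.6 (SD, n = 5) and 107 ± 24.0 CPM (n = 4), and the difference was not called (adjusted p = 0.11). En1, which encodes a homeobox transcription factor, ran the other way: it stayed at or below 0.57 CPM in all 21 ductal-derived cultures and exceeded 1 CPM in 22 of the 27 acinar-derived ones.

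**Figure D1:**
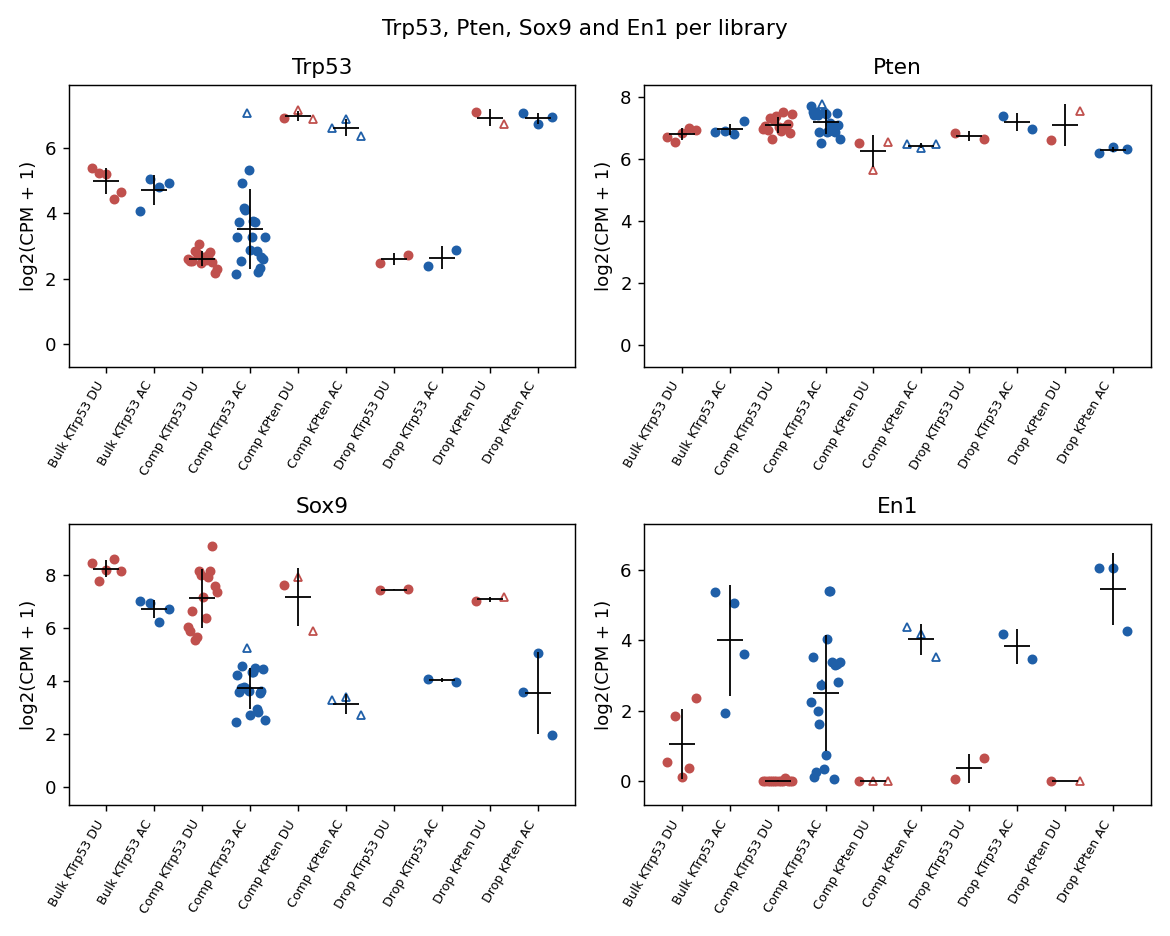
Trp53, Pten, Sox9 and En1 in each library, as log2(CPM + 1), for the 10 groups on the x axis. Filled circles are libraries labelled with both alleles floxed and open triangles those with 1, red is ductal-derived and blue acinar-derived, and black bars give the group mean and SD. Sox9 lay at 45.5 CPM or more in all ductal-derived cultures and at 36.8 CPM or less in all acinar-derived ones.

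Origin was compared first in bulk KTrp53 tumours. The zinc finger transcription factor Sall1 (ENSMUSG00000031665.6, chromosome 8, 89027235 to 89044162) was higher with ductal origin, at 14.4 ± 4.72 CPM (SD, n = 5) against 0.369 ± 0.106 CPM (n = 4), a log2 fold change of 5.25 ± 0.41 (adjusted p = 0.0032). Digestive enzyme genes and their regulators had higher values in ductal-derived tumours: 25 of 30 measured were higher adjusted over the list alone, while 30 were not called over all genes (adjusted p = 2.9e-16; adjusted p = 0.73 with an estimated correlation). Among them the chymotrypsin-like enzyme Ctrl differed by 7.63 ± 1.79 (adjusted p = 0.24), the lipase Pnlip by 9.55 ± 2.46 (adjusted p = 0.26) and the acinar transcription factor Rbpjl by 5.07 ± 1.17 (adjusted p = 0.24). Islet hormone genes had the same direction, with 5 of 13 higher adjusted over the list alone and a median log2 fold change of 3.75 (adjusted p = 0.00091; adjusted p = 0.73 with an estimated correlation). Ins1 differed by 8.45 ± 2.60 (adjusted p = 0.29). The list mean was 7.77 and 4.96 log2 CPM in ductal-derived tumours 2 and 3, and -1.82 to 1.86 in the other 3 against -3.32 to 2.07 in the acinar-derived tumours.

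Interferon-stimulated and MHC class I genes had a median log2 fold change of 1.26 toward the ductal-derived tumours, and 15 of 25 were higher adjusted over the list alone (adjusted p = 1.5e-13; adjusted p = 0.73 with an estimated correlation). Usp18 differed by 2.51 ± 0.44 (adjusted p = 0.13) and Isg15 by 2.17 ± 0.54 (adjusted p = 0.26). Macrophage markers had a median of 0.66, without a member past the threshold on either scale (adjusted p = 0.00039; adjusted p = 0.73 with an estimated correlation). Genes of the classical PDAC subtype had a median of -1.47, 4 of 21 being lower adjusted over the list alone (adjusted p = 4.1e-09; adjusted p = 0.73 with an estimated correlation). Cldn18, a tight junction protein of gastric epithelium, differed by -7.59 ± 1.21 (adjusted p = 0.11) and the keratin Krt20 by -3.31 ± 0.72 (adjusted p = 0.22). Among gastric mucous genes 5 of 16 were lower and 1 higher adjusted over the list alone (adjusted p = 4.0e-05; adjusted p = 0.73 with an estimated correlation), with Muc6 at -4.47 ± 1.01 (adjusted p = 0.23) and Gif at 9.14 ± 1.83 (adjusted p = 0.24).

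Over all 15816 genes, edgeR called 1 gene, Sall1. At an unadjusted p under 0.05 there were 2125, and DESeq2 called 497. Without acinar-derived tumour 2 edgeR called 45 genes and without acinar-derived tumour 3 it called 2. Fitted together with all other libraries, the same comparison gave 159.

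**Figure D2:**
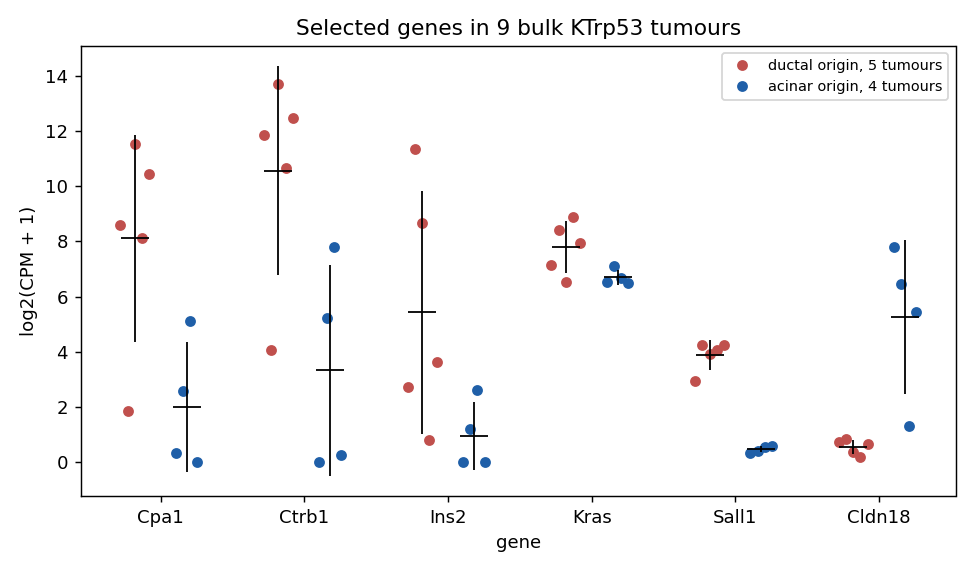
Cpa1, Ctrb1, Ins2, Kras, Sall1 and Cldn18 in the 9 bulk KTrp53 tumours, as log2(CPM + 1) per tumour with the group mean and SD, red for 5 ductal-derived and blue for 4 acinar-derived tumours. The digestive enzyme genes Cpa1 and Ctrb1 spread widely within the ductal-derived group, while Sall1 separated the origins.

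In complete medium, acinar-derived KTrp53 cultures were on average higher in gastric mucous and classical PDAC genes than ductal-derived ones. Gkn1, a secreted protein of gastric surface cells, lay at 26.7 ± 42.1 CPM (SD, n = 19) against 0.0154 ± 0.0311 CPM (n = 14), and fell by 10.42 ± 1.17 on the log2 scale from acinar to ductal origin (adjusted p = 1.4e-07). The values were -10.51 ± 1.28 for Gkn2, -9.33 ± 1.21 for the trefoil peptide gene Tff1 and -7.69 ± 1.13 for Cldn18. Of 13 gastric mucous genes 10 were lower and 3 not called (11 lower adjusted over the list alone; adjusted p = 4.4e-15, and adjusted p = 0.0018 with an estimated correlation). Of 21 classical PDAC genes 14 were lower and 7 not called (17 lower adjusted over the list alone; adjusted p = 3.5e-14, and adjusted p = 0.0084 with an estimated correlation), among them Krt20 at -5.36 ± 0.59 (adjusted p = 1.8e-08) and Anxa10 at -4.90 ± 0.59 (adjusted p = 1.4e-07). En1 (chromosome 1, 120602418 to 120607992) fell by 9.92 ± 0.99 and Prap1 by 7.38 ± 1.03.

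Ductal-derived cultures were higher in Tnik (chromosome 3, 28263214 to 28675858), a kinase of Wnt signalling, at 51.2 ± 15.2 CPM (n = 14) against 3.04 ± 2.72 CPM (n = 19), a log2 fold change of 4.10 ± 0.34 (adjusted p = 2.4e-11). The matrix glycoprotein gene Tnc rose by 3.98 ± 0.77, Gxylt2 by 4.38 ± 0.72, Sfmbt2 by 3.45 ± 0.48 and Acap1 by 3.68 ± 0.94. Interferon and MHC class I genes had 11 of 25 higher and 1 lower, with 13 higher and 1 lower adjusted over the list alone (adjusted p = 2.0e-11; adjusted p = 0.22 with an estimated correlation). Ifit2 rose by 2.81 ± 0.46 (adjusted p = 3.2e-05) and Bst2 by 1.53 ± 0.29 (adjusted p = 0.00023).

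Targets of p53 were lower in ductal-derived cultures, with 12 of 25 lower over all genes and adjusted over the list alone (adjusted p = 3.4e-05; adjusted p = 0.19 with an estimated correlation), led by Gdf15 at -2.94 ± 0.59 (adjusted p = 0.00050) and Ccng1 at -1.27 ± 0.29 (adjusted p = 0.0021). Trp53 itself differed by -1.77 ± 0.39 (adjusted p = 0.0014), and by -1.12 ± 0.26 (adjusted p = 0.0025) without acinar-derived 8, which is labelled with 1 floxed allele. Without that culture 10 of the 25 targets were lower (adjusted p = 0.00024; adjusted p = 0.18 with an estimated correlation), and Trp53 lay at 11.4 ± 9.58 CPM (SD, n = 18) in the acinar-derived group. Glucocorticoid targets had 10 of 20 lower, with 10 lower and 1 higher adjusted over the list alone (adjusted p = 4.2e-05; adjusted p = 0.22 with an estimated correlation). Early stress and heat shock genes had 8 of 18 lower, 10 adjusted over the list alone (adjusted p = 1.5e-05; adjusted p = 0.19 with an estimated correlation), such as Hspa1a at -2.31 ± 0.52 (adjusted p = 0.0017). These lists moved with batch: the glucocorticoid list mean was lower with ductal origin by a difference in log2 CPM of -0.63 over all libraries and of -0.31, -0.29 and -0.56 within batches A, B and C, and the early stress mean by -0.84, and by -0.27, -0.55 and -0.76. NRF2 targets had 6 of 20 lower on both scales (adjusted p = 0.0030; adjusted p = 0.36 with an estimated correlation), with Nqo1 at -3.56 ± 0.61 (adjusted p = 6.5e-05), and their mean differed by 0.17, -0.25 and -1.01 within batches A, B and C. Macrophage markers had 7 of 14 lower, 10 adjusted over the list alone (adjusted p = 0.0016; adjusted p = 0.19 with an estimated correlation), from low levels: Lyz2 lay at 1.15 ± 1.93 CPM (n = 19) against 0.0359 ± 0.0524 CPM (n = 14).

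In all, 2327 of 16567 genes were called, 957 higher and 1370 lower with ductal origin. Y-linked expression was not balanced: Ddx3y exceeded 20 CPM in 11 of 14 ductal-derived and 6 of 19 acinar-derived libraries, and the sex-linked list had 1 of 4 higher (adjusted p = 0.0030; adjusted p = 0.26 with an estimated correlation). In a fit of these 2 groups 1432 genes were called, and 794 with Ddx3y class as a term, chosen after the data were seen. Within batches A, B and C, 77, 343 and 257 genes were called, and 91.1%, 96.5% and 98.0% of the pooled calls tested there had the pooled sign. Each batch is part of the pooled libraries, so these shares are high in part by construction. With batch as a term, in a fit of these 2 groups, 1229 were called. Tnik passed in every batch (4.88 ± 0.58, 4.54 ± 0.25 and 3.94 ± 0.57), as did Sox9 (2.40 ± 0.34, 3.92 ± 0.45 and 4.49 ± 0.43). Tff1 passed in batch A (-8.32 ± 0.99, adjusted p = 0.010) and had the same direction in B (-7.35 ± 1.82, adjusted p = 0.053) and C (-9.81 ± 2.64, adjusted p = 0.075). Gxylt2 differed by 4.72 ± 0.95 in B and 0.05 ± 0.34 in C. Acap1 was lower with ductal origin in A (-3.53 ± 0.50, adjusted p = 0.022) and did not pass in B (-0.85 ± 0.45, adjusted p = 0.43) or C (4.76 ± 1.20, adjusted p = 0.061). The mean of the interferon and MHC class I list was higher with ductal origin by a log2 CPM difference of 0.46, 3.02 and 1.65 in A, B and C, and 1.75 over all libraries. The proliferation gene Mki67, named after its values were seen, differed between batches, at 312 ± 166 CPM (n = 4) and 235 ± 78.8 CPM (n = 9) in ductal-derived and acinar-derived cultures of batch C against group means of 535 to 639 CPM in A and B.

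Origin was also compared in complete-medium KPten cultures, 3 against 3. Besides Sox9, ductal-derived cultures were higher in Serpinh1, a collagen chaperone (chromosome 7, 99345376 to 99353239), at 32.3 ± 11.1 CPM (SD, n = 3) against 2.45 ± 2.11 CPM (n = 3), a log2 fold change of 3.71 ± 0.81 (adjusted p = 0.030). En1 was at least 298-fold lower, with no count in 3 ductal-derived libraries and 15.8 ± 4.70 CPM (n = 3) in acinar-derived ones (adjusted p = 0.023), and Krt20 fell by 6.43 ± 1.40 (adjusted p = 0.030). Dlgap1 (-4.34 ± 0.85), Cpne2 (-2.17 ± 0.41) and the glycosyltransferase gene Galnt1 (-1.96 ± 0.37) also fell. Tpm3-rs7 and Eno1b, both copies of other genes and so uncertain, had values of 5.29 ± 0.88 and 9.93 ± 1.97. The classical PDAC list had 1 of 21 lower, 2 adjusted over the list alone, and was not called (adjusted p = 0.36). Cholesterol synthesis genes had a median of -0.28 (adjusted p = 0.00074; adjusted p = 0.96 with an estimated correlation), with Idi1 lower adjusted over the list alone (-1.59 ± 0.46, adjusted p = 0.29 over all genes). NRF2 targets had a median of -0.22 with no member past either threshold (adjusted p = 0.028; adjusted p = 0.96 with an estimated correlation).

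Here 24 genes were called, 16 higher and 8 lower, 554 had an unadjusted p under 0.05, and DESeq2 called 76. A fit of only these groups also called 24, 10 higher and 14 lower, with 1842 of 13249 genes at an unadjusted p under 0.05. Leaving out acinar-derived culture 1, 2 or 3 gave 10, 9 and 11 calls, and protein-coding genes tested alone gave 9. All 3 acinar-derived cultures are labelled with 1 floxed Pten allele, as are 2 of the 3 ductal-derived ones.

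In dropout medium, ductal-derived KTrp53 cultures were more epithelial than acinar-derived ones. Of 22 epithelial junction genes 9 were higher and 13 not called, with 17 higher adjusted over the list alone (adjusted p = 1.8e-21; adjusted p = 0.15 with an estimated correlation). The adaptor gene Ap1m2 rose by 4.59 ± 0.67 (adjusted p = 0.00029), from 3.16 ± 1.25 CPM (SD, n = 2) to 74.6 ± 2.51 CPM (n = 2), and Rab25 by 4.48 ± 0.73 (adjusted p = 0.00084). The epithelial transcription factor gene Grhl2 rose by 3.67 ± 0.57. Keratin Krt6a (chromosome 15, 101689910 to 101694307) rose by 8.81 ± 1.55 (adjusted p = 0.0013) and the matrix protease gene Mmp7 by 7.62 ± 1.89 (adjusted p = 0.024). Sult4a1, Lpcat2 and Cxcl14 had no count in the 2 acinar-derived cultures and were at least 147-, 70.0- and 48.6-fold higher. Basal-like PDAC genes had 4 of 24 higher, with 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.00032; adjusted p = 0.15 with an estimated correlation). Duct markers had 2 of 22 higher, 7 adjusted over the list alone (adjusted p = 0.00039; adjusted p = 0.19 with an estimated correlation), including Cldn4 at 4.33 ± 1.01 (adjusted p = 0.014).

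Lower with ductal origin were Avil, an actin-binding protein, by a log2 fold change of -7.11 ± 1.74, the collagen-binding integrin Itga1 (-5.33 ± 1.32) and Pcolce, which promotes collagen processing (-4.87 ± 1.21). Glycolysis and hypoxia genes had 5 of 26 lower, 7 adjusted over the list alone (adjusted p = 3.0e-11; adjusted p = 0.17 with an estimated correlation), such as Pfkp at -2.31 ± 0.48 (adjusted p = 0.0070). Gastric mucous genes had a median of -4.69, with 7 of 13 lower adjusted over the list alone and 13 not called over all genes (adjusted p = 0.00019; adjusted p = 0.17 with an estimated correlation). Classical PDAC genes had 6 of 21 lower adjusted over the list alone and 21 not called over all genes (adjusted p = 4.9e-06; adjusted p = 0.17 with an estimated correlation). Mesenchymal genes had a median of -1.90 and 20 not called on either scale (adjusted p = 0.014; adjusted p = 0.54 with an estimated correlation).

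This comparison of 2 against 2 cultures called 298 genes, 205 higher and 93 lower, against 2324 at an unadjusted p under 0.05, 818 by DESeq2 and 84 in a fit of only these groups. It rested on each library: 11 and 160 genes were called without acinar-derived culture 1 or 2, and 100 and 75 without ductal-derived culture 1 or 2.

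In dropout medium the KPten cultures showed the opposite picture. Ductal-derived KPten cultures were higher in mesenchymal and matrix genes than acinar-derived ones: of 20 mesenchymal genes 13 were higher and 7 not called, also adjusted over the list alone (adjusted p = 1.6e-15, and adjusted p = 0.012 with an estimated correlation). Sparc, a matrix glycoprotein (chromosome 11, 55394500 to 55423183), rose by 14.25 ± 2.52 (adjusted p = 0.00012) and the matrix crosslinking enzyme gene Lox by 9.31 ± 1.66 (adjusted p = 0.00013). The growth factor receptor gene Pdgfrb (chromosome 18, 61045150 to 61085061) lay at 209 ± 93.3 CPM (SD, n = 2) and the collagen receptor gene Mrc2 at 203 ± 127 CPM (n = 2), with no count in 3 acinar-derived cultures, at least 5049- and 4910-fold higher. Fibroblast markers had 8 of 20 higher, 9 adjusted over the list alone (adjusted p = 1.6e-07, and adjusted p = 0.036 with an estimated correlation), including Ogn at 11.14 ± 1.59 (adjusted p = 7.2e-06).

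Epithelial junction genes fell with ductal origin, 20 of 22 being lower and 21 adjusted over the list alone (adjusted p = 6.8e-24, and adjusted p = 0.036 with an estimated correlation), with Rab25 at -3.62 ± 0.68 (adjusted p = 0.00024) and Grhl2 at -2.93 ± 0.53 (adjusted p = 0.00017). The endoderm transcription factor gene Sox17 and En1 had no count in the 2 ductal-derived cultures and were at least 1494- and 841-fold lower, and Ltf, which encodes lactoferrin, fell by 8.38 ± 1.94. Duct markers had 10 of 22 lower and 3 higher, with 11 lower and 3 higher adjusted over the list alone (adjusted p = 0.0021; adjusted p = 0.30 with an estimated correlation), with Krt7 at -3.27 ± 0.63 and the secreted phosphoprotein gene Spp1 at 3.83 ± 0.68. The Y-linked Ddx3y had no count in the 3 acinar-derived cultures and was at least 2631-fold higher in the ductal-derived ones, so the sex of the animals or loss of the Y chromosome in culture moved with origin in this comparison.

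The comparison called 2022 genes, 1106 higher and 916 lower, and 480 without ductal-derived culture 2, which is labelled with 1 floxed allele. Whether the origin effects differ between genotypes in dropout medium was tested after the result was seen: 1767 genes differed, 901 higher and 866 lower, and 761 without ductal-derived KPten culture 2. Without ductal-derived or acinar-derived KTrp53 culture 1 the counts were 1053 and 1185, and without ductal-derived KTrp53 culture 2 the count was 1082. Epithelial junction genes had 21 of 22 lower in that test (adjusted p = 8.8e-33, and adjusted p = 0.016 with an estimated correlation) and mesenchymal genes 12 of 20 higher (adjusted p = 5.2e-13, and adjusted p = 0.016 with an estimated correlation).

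**Figure D3:**
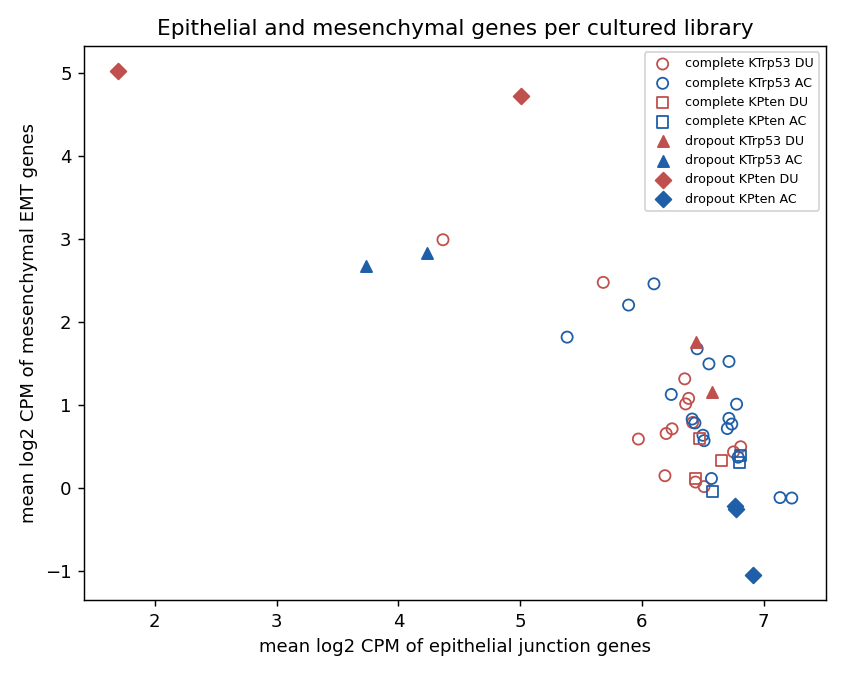
Mean log2 CPM of the epithelial junction genes (x axis) against that of the mesenchymal genes (y axis) in each of the 48 cultured libraries. Symbols give medium and genotype, red is ductal-derived and blue acinar-derived, with filled symbols for dropout medium. The 2 ductal-derived KPten dropout cultures had the highest mesenchymal means and the 3 acinar-derived ones the lowest.

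Across the 5 settings, origin effects were compared gene by gene, and genes are not independent replicates. The log2 fold changes of complete-medium KTrp53 cultures correlated with those of bulk tumours (Pearson r = 0.33 over 14788 genes, Spearman rho = 0.26), complete-medium KPten (r = 0.26, rho = 0.25), dropout KTrp53 (r = 0.29, rho = 0.22) and dropout KPten cultures (r = 0.16, rho = 0.16). Between the dropout KTrp53 and KPten cultures r was -0.15 and rho -0.16, and 99 genes were called in opposite directions against 6 called higher and 6 called lower in both, where independent lists would share 13.7 and 5.14. Complete-medium KTrp53 and dropout KPten cultures shared 144 higher and 176 lower calls (63.9 and 75.7 for independent lists), with 85 opposite. No gene was called in the same direction by edgeR in all 4 culture settings. At an unadjusted p under 0.05 there were 4781 genes in complete-medium KTrp53, 554 in complete-medium KPten, 2324 in dropout KTrp53 and 4172 in dropout KPten cultures, with 2327, 24, 298 and 2022 called.

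Genotypes were compared in complete medium over both origins. Targets of p53 were higher in KPten than in KTrp53 cultures, 18 of 25 being higher, 2 lower and 5 not called, with 20 higher and 2 lower adjusted over the list alone (adjusted p = 8.8e-15, and adjusted p = 0.014 with an estimated correlation). Phlda3 rose by 3.05 ± 0.25 (adjusted p = 2.6e-12), with 149 ± 26.4 (SD, n = 3) and 131 ± 1.81 CPM (n = 3) in KPten against 11.6 ± 4.69 (n = 14) and 24.0 ± 22.7 CPM (n = 19) in KTrp53 cultures. Ccng1 rose by 2.98 ± 0.29, the DNA polymerase gene Polk by 1.36 ± 0.14 and the apoptosis gene Bax by 1.99 ± 0.20. Trp53 itself was higher by 3.53 ± 0.38 (adjusted p = 2.1e-09).

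Classical PDAC genes had 9 of 21 lower in KPten, 10 adjusted over the list alone (adjusted p = 0.0034; adjusted p = 0.84 with an estimated correlation), such as Lgals4 at -5.82 ± 1.01 (adjusted p = 3.1e-05). Basal-like PDAC genes had 7 of 24 higher on both scales (adjusted p = 0.0068; adjusted p = 0.42 with an estimated correlation), led by Fam83a at 5.10 ± 0.46 (adjusted p = 2.7e-11). Interferon and MHC class I genes had 13 of 25 lower and 1 higher, with 14 lower and 1 higher adjusted over the list alone (adjusted p = 0.031; adjusted p = 0.84 with an estimated correlation), Cxcl10 falling by 4.41 ± 0.78. Their mean in log2 CPM was 1.87 to 3.40 in ductal-derived KPten against 4.62 ± 1.17 (SD, n = 14) in ductal-derived KTrp53 cultures. In acinar-derived cultures it was 2.13 to 3.06 against 2.86 ± 1.35 (n = 19), so the average over origins hides a split. Cell cycle genes had 7 of 26 lower on both scales and mitochondrial messenger RNAs 8 of 13 (adjusted p = 0.031 for each list; adjusted p = 0.84 with an estimated correlation). These lists varied with batch in KTrp53 cultures. Cell cycle means lay at 6.57 to 6.97 log2 CPM in KPten cultures, below batches A and B (7.27 to 7.80) but above the mean of 6.44 ± 0.46 (SD, n = 9) of acinar-derived batch C. Mitochondrial means of 10.06 to 10.43 lay within the 9.15 to 10.64 of ductal-derived batch A. FOXO targets, which respond to signalling downstream of Pten, had 6 of 20 lower and 1 higher on both scales, and the list was not called (adjusted p = 0.25). Among single genes, Myrip (-11.94 ± 1.78), the transcription factor gene Foxf2 (-8.40 ± 2.18) and the adenosine receptor gene Adora1 (-8.00 ± 1.70) fell, while the channel gene Ano3 rose by 4.94 ± 0.70. The Y-linked genes Ddx3y (-8.62 ± 2.36) and Eif2s3y (-8.79 ± 2.42) were lower, from an imbalance in the sex of the animals or in loss of the Y chromosome in culture. Hist1h2ap, Vcp-rs, Idi2, Rps12, Eno1b and Rps12l1 had some of the most extreme fold changes, are copies or near-copies of other genes and are uncertain.

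The comparison called 4701 of 16567 genes, 1933 higher and 2768 lower. Against the KTrp53 libraries of batch A or B alone it called 7267 and 7709. KPten and KTrp53 libraries may also differ in preparation, which was not tested.

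In dropout medium the genotypes differed in 3325 genes, 1464 higher and 1861 lower in KPten. Targets of p53 were again higher, 10 of 25 over all genes and 11 adjusted over the list alone (adjusted p = 2.3e-05; adjusted p = 0.24 with an estimated correlation), with Ccng1 at 3.57 ± 0.61 (adjusted p = 5.7e-05) and Ercc5 at 1.52 ± 0.24 (adjusted p = 1.2e-05). Targets of cAMP and CREB were lower in 7 of 18, 11 adjusted over the list alone (adjusted p = 1.4e-05; adjusted p = 0.10 with an estimated correlation), among them the cAMP phosphodiesterase genes Pde4d (-2.91 ± 0.30, adjusted p = 9.4e-09) and Pde3b (-4.66 ± 0.53, adjusted p = 6.2e-08). MAPK output genes had 11 of 22 lower and 1 higher on both scales (adjusted p = 0.00082; adjusted p = 0.24 with an estimated correlation), such as Hbegf at -1.91 ± 0.37 (adjusted p = 0.00026). Amino acid response genes had 7 of 24 lower on both scales (adjusted p = 0.00054; adjusted p = 0.59 with an estimated correlation), with the transporter gene Slc7a3 at -5.80 ± 0.90 (adjusted p = 1.2e-05). NRF2 targets had 6 of 20 higher and 1 lower, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.0090; adjusted p = 0.70 with an estimated correlation). Classical PDAC genes had 4 of 21 lower, 7 adjusted over the list alone (adjusted p = 0.00054; adjusted p = 0.34 with an estimated correlation).

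The cartilage proteoglycan gene Acan (chromosome 7, 79053483 to 79115099) fell by 10.42 ± 1.06, from 131 ± 68.0 (SD, n = 2) and 440 ± 54.9 CPM (n = 2) in KTrp53 to group means of 0.29 (n = 2) and 0.097 CPM (n = 3) in KPten cultures. The adaptor gene Grb10 fell by 10.90 ± 1.66 and Epb41l3 by 8.27 ± 1.71. Klhl4 rose by 13.30 ± 1.82, the haptoglobin gene Hp by 7.09 ± 2.28 and the cytochrome P450 gene Cyp2f2 by 9.78 ± 2.08. Without ductal-derived KPten culture 2 the count was 1797 and without ductal-derived KTrp53 culture 1 it was 1919.

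Medium was compared within each genotype. In KTrp53 cultures, cholesterol synthesis genes were on average lower and amino acid response genes higher in dropout than in complete medium. Of 24 cholesterol synthesis genes 14 fell, 17 adjusted over the list alone (adjusted p = 1.4e-08; adjusted p = 0.38 with an estimated correlation), including Hmgcs1 by 1.71 ± 0.24 (adjusted p = 1.4e-06) and Hmgcr, which encodes the rate-limiting enzyme, by 1.39 ± 0.20 (adjusted p = 3.2e-06). The list mean was 6.69 and 6.94 log2 CPM in ductal-derived dropout cultures, against 7.46 ± 0.094 (SD, n = 6) in ductal-derived complete-medium cultures of batch A but 6.97 ± 0.46 (n = 4) in those of batch C. It was 6.76 and 6.12 in acinar-derived dropout cultures, against 7.29 to 7.69 in batches A and B and 6.52 to 7.99 in batch C. Of 24 ATF4 and amino acid response genes 13 rose on both scales (adjusted p = 9.4e-07; adjusted p = 0.38 with an estimated correlation), with Atf5 at 2.37 ± 0.26 (adjusted p = 2.0e-08) and Trib3 at 2.42 ± 0.37 (adjusted p = 6.1e-06). The list mean was 7.73 to 7.80 log2 CPM in 3 dropout cultures and 6.12 in ductal-derived culture 2, within the 5.56 to 6.78 of ductal-derived complete-medium cultures. Epithelial junction genes had 11 of 22 lower, 16 adjusted over the list alone (adjusted p = 9.4e-07; adjusted p = 0.61 with an estimated correlation). Their mean in log2 CPM was 3.74 and 4.24 in the acinar-derived dropout cultures (5.39 to 7.23 in complete medium), but 6.57 and 6.44 in the ductal-derived ones (4.37 to 6.81). Basal-like PDAC genes had 9 of 24 lower and 2 higher on both scales (adjusted p = 0.0090; adjusted p = 0.38 with an estimated correlation), Krt6a falling by 5.22 ± 0.87. Their mean in log2 CPM was 1.09 and 1.47 in the acinar-derived dropout cultures (3.01 to 4.24 in complete medium), but 2.81 and 3.23 in the ductal-derived ones (1.79 to 4.39). NRF2 targets had 7 of 20 lower, 8 adjusted over the list alone (adjusted p = 0.0054; adjusted p = 0.62 with an estimated correlation). Neutrophil-list genes, some of which epithelial cells also express, had 3 of 8 lower, 4 adjusted over the list alone (adjusted p = 0.019; adjusted p = 0.38 with an estimated correlation).

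The dual oxidase gene Duox2 (chromosome 2, 122279247 to 122298449) fell by 9.46 ± 1.48, and its maturation factor gene Duoxa2 had a value of -9.63 ± 1.69. Duox2 lay at 90.6 ± 83.2 (SD, n = 14) and 433 ± 429 CPM (n = 19) in complete and at 0.237 ± 0.269 (n = 2) and 0.310 ± 0.107 CPM (n = 2) in dropout medium. The cornified envelope gene Sprr2d (-10.02 ± 1.59), the surfactant protein gene Sftpd (-9.48 ± 1.21) and the amino acid transporter gene Slc6a14 (-9.38 ± 1.49) fell. The matrix gene Tnxb rose by 5.73 ± 0.87, the phospholipase gene Plce1 by 3.24 ± 0.49 and Fer1l6 by 3.22 ± 0.49. In all 3787 genes were called, 1631 higher and 2156 lower. The count fell to 1583 and 2465 without ductal-derived dropout culture 1 or 2 and to 1886 without acinar-derived dropout culture 2, and rose to 6890 and 7168 against complete-medium libraries of batch A or B alone.

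In KPten cultures cAMP and CREB targets were lower in dropout than in complete medium, 11 of 18 on both scales (adjusted p = 1.1e-08, and adjusted p = 0.014 with an estimated correlation). Pde4d fell by 4.10 ± 0.31 (adjusted p = 1.6e-12), Pde4b by 6.68 ± 0.62 (adjusted p = 4.3e-10) and the kinase gene Sik1 by 2.13 ± 0.37 (adjusted p = 6.0e-05). Pde4b lay at 73.0 ± 24.0 (SD, n = 3) and 71.4 ± 21.2 CPM (n = 3) in complete and 8.19 ± 7.24 (n = 2) and 0.0551 ± 0.063 CPM (n = 3) in dropout medium. Epithelial junction genes had 12 of 22 lower, 16 adjusted over the list alone (adjusted p = 4.3e-09; adjusted p = 0.49 with an estimated correlation), and basal-like genes 9 of 24 lower and 1 higher on both scales (adjusted p = 0.00014; adjusted p = 0.096 with an estimated correlation). Mesenchymal genes had 4 of 20 higher, 8 adjusted over the list alone (adjusted p = 0.00012; adjusted p = 0.49 with an estimated correlation). Both averages over origin hide a split. The epithelial junction mean in log2 CPM was 5.01 and 1.70 in the ductal-derived dropout cultures (6.44 to 6.65 in complete medium) but 6.76 to 6.92 in acinar-derived ones (6.58 to 6.81). The mesenchymal mean was 4.72 and 5.02 in the former (0.121 to 0.593) and -1.05 to -0.21 in the latter (-0.0382 to 0.394). Ddx3y also set the ductal-derived cultures apart, at most at 0.200 CPM in complete and at 77.7 CPM or more in dropout medium. They may therefore come from different animals, and the split cannot be read as an effect of medium alone. Cholesterol synthesis genes had 7 of 24 lower and 1 higher, with 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.0079; adjusted p = 0.66 with an estimated correlation). Duct markers had 8 of 22 lower and 2 higher, with 9 lower and 2 higher adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.62 with an estimated correlation). The chloride channel gene Cftr fell by 4.68 ± 0.76 and Spp1 rose by 3.29 ± 0.46.

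The receptor tyrosine kinase gene Kit (chromosome 5, 75574916 to 75656722) fell by 8.72 ± 1.08. Sprr2d (-12.71 ± 1.86) and the amino acid transporter gene Slc7a8 (-8.87 ± 1.56) fell as well, while Klhl4 rose by 10.99 ± 1.32, the matrix protein gene Ogn by 8.96 ± 1.39 and the transcription factor gene Nr2f1 by 7.40 ± 1.25. In all 3316 genes were called, 1421 higher and 1895 lower, and 1466 without ductal-derived dropout culture 2. With the replicate number as a block, in a fit of these 4 groups, 5060 were called, against 6491 in the same fit without the block. The block also joined the ductal-derived pairs, for which the pairing did not meet the rule. Of the lists, interferon and MHC class I genes were called in that fit without the block (adjusted p = 0.039) and not with it (adjusted p = 0.15), and no other list call differed. With and without the block, the fits of these 4 groups did not call duct markers (adjusted p = 0.059 and 0.079) and called p53 targets, cell cycle, neutrophil-list and sex-linked genes (adjusted p at most 0.013). The labels give acinar-derived cultures 1 floxed Pten allele in complete and both in dropout medium, so medium and allele number coincide there. Rpl39-ps lay at 57.0 to 71.6 CPM in complete and at 1.66 to 6.02 CPM in dropout KPten cultures, so by this pseudogene medium coincides with a separate library set too. The differences between media in KPten cultures therefore cannot be assigned to medium alone.

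**Figure D4:**
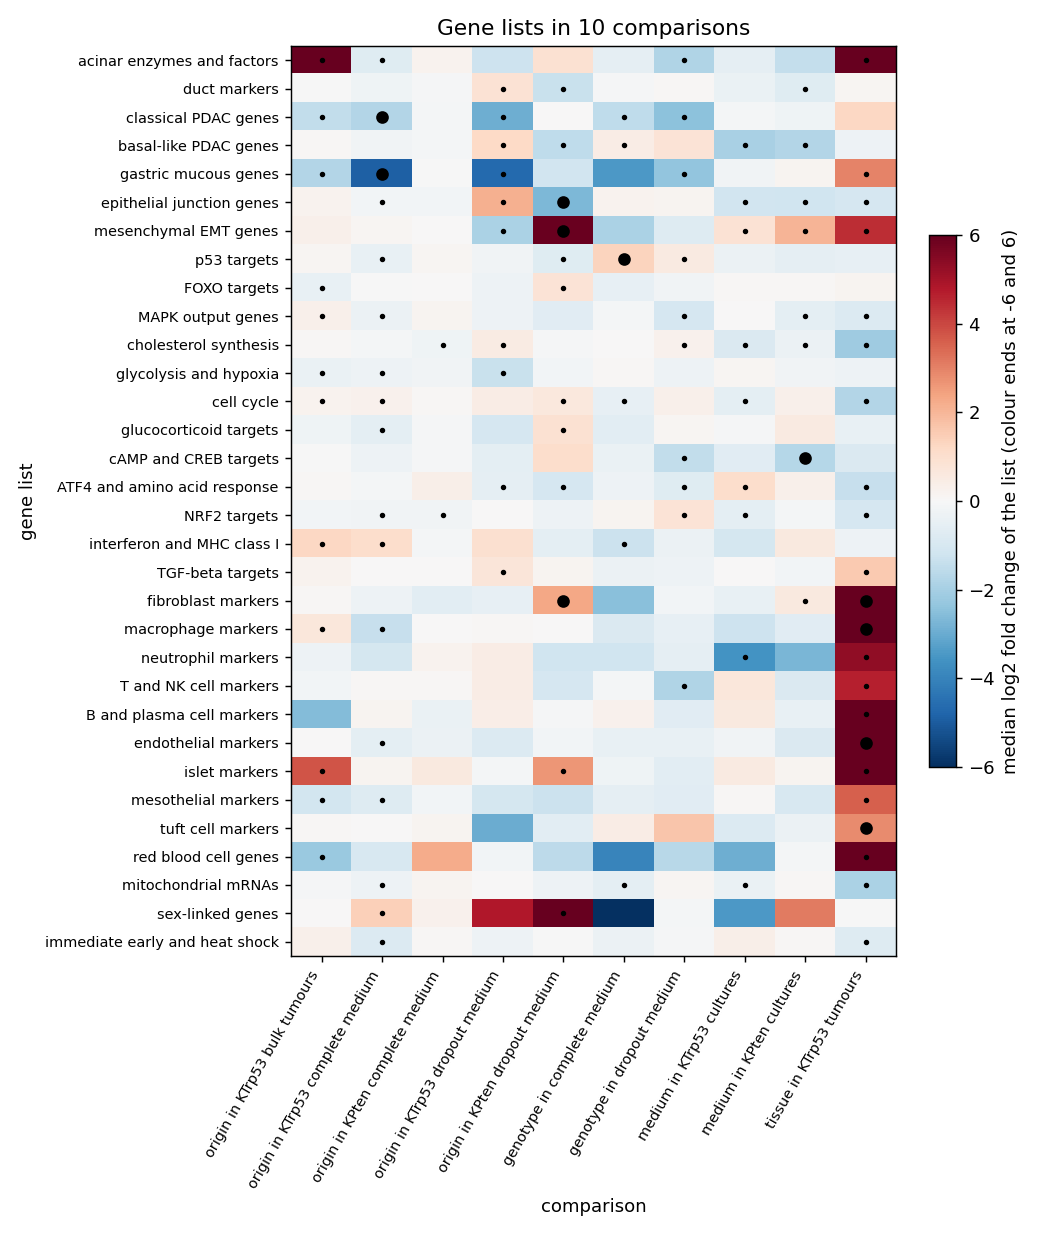
Median log2 fold change of the 32 gene lists (y axis) in 10 comparisons (x axis), red for higher and blue for lower, with the colour scale ending at -6 and 6. Small dots mark lists called with the preset correlation and large dots those also called with an estimated correlation.

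Bulk KTrp53 tumours were compared with complete-medium KTrp53 cultures over both origins. Bulk tumours were higher in markers of other cell types. All 22 fibroblast markers were higher (adjusted p = 1.0e-11, and adjusted p = 0.023 with an estimated correlation), as were 17 of 18 macrophage markers (adjusted p = 7.4e-13, and adjusted p = 0.015 with an estimated correlation), with the same counts adjusted over the list alone. Thy1 rose by 10.04 ± 0.34 (adjusted p = 4.5e-26) and the leukocyte gene Ptprc by 8.27 ± 0.28 (adjusted p = 3.2e-26). Endothelial markers had 15 of 17 higher and 1 lower (adjusted p = 3.0e-09, and adjusted p = 0.041 with an estimated correlation), and tuft cell markers 9 of 10 higher (adjusted p = 0.00024, and adjusted p = 0.023 with an estimated correlation), led by Hck, Plcb2 and Alox5ap, which immune cells also express. Digestive enzyme genes had 29 of 30 higher (adjusted p = 3.2e-09; adjusted p = 0.27 with an estimated correlation), Ctrb1 by 13.79 ± 0.72 and Cpa1 by 14.12 ± 0.92. B and plasma cell markers had 14 of 14 higher (adjusted p = 2.5e-06; adjusted p = 0.19 with an estimated correlation), and the immunoglobulin genes Igha and Igkc rose by 15.92 ± 0.49 and 14.88 ± 0.52. T and NK cell markers had 16 of 17 higher (adjusted p = 2.1e-06; adjusted p = 0.16 with an estimated correlation) and islet markers 12 of 13 (adjusted p = 0.00090; adjusted p = 0.32 with an estimated correlation). Mesenchymal genes had 20 of 21 higher (adjusted p = 2.5e-08; adjusted p = 0.064 with an estimated correlation), neutrophil markers 10 of 12 higher and 1 lower (adjusted p = 0.00021; adjusted p = 0.064 with an estimated correlation), TGF-beta targets 11 of 18 higher and 1 lower (adjusted p = 0.00080; adjusted p = 0.080 with an estimated correlation) and mesothelial markers 7 of 11 higher and 2 lower (adjusted p = 0.044; adjusted p = 0.27 with an estimated correlation). For these lists the counts adjusted over the list alone were the same. Red blood cell genes had 5 of 6 higher, 6 adjusted over the list alone (adjusted p = 0.00080; adjusted p = 0.16 with an estimated correlation), and sex-linked genes had none called (adjusted p = 0.96).

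In bulk tumours 26 of 26 cell cycle genes were lower (adjusted p = 2.1e-09; adjusted p = 0.27 with an estimated correlation), with Aurkb at -2.18 ± 0.18 and Ccnb2 at -2.36 ± 0.22. Cholesterol synthesis genes had 23 of 24 lower (adjusted p = 3.0e-12; adjusted p = 0.064 with an estimated correlation), Msmo1 falling by 2.93 ± 0.17 and Ldlr by 2.57 ± 0.16. Amino acid response genes had 20 of 24 lower and 1 higher (adjusted p = 7.6e-05; adjusted p = 0.18 with an estimated correlation), NRF2 targets 14 of 20 lower and 1 higher (adjusted p = 0.00060; adjusted p = 0.27 with an estimated correlation) and mitochondrial messenger RNAs 13 of 13 lower (adjusted p = 2.5e-06; adjusted p = 0.19 with an estimated correlation). These counts too were the same adjusted over the list alone. Sprr2d (-12.48 ± 1.30), Cnfn (-9.94 ± 1.11) and Slc6a14 (-8.42 ± 0.87) fell. The comparison called 11643 of 16978 genes, 5850 higher and 5793 lower in bulk.

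Finally, origin effects were compared between genotypes and between tissue and culture. Between KPten and KTrp53 in complete medium, 6 genes had a different origin effect, all 6 higher in the ductal minus acinar difference of KPten, with 586 at an unadjusted p under 0.05 and 38 by DESeq2. Those named by the rule are Tpm3-rs7 (5.23 ± 0.91) and Eno1b (9.93 ± 2.03), both uncertain copies, and neither stayed called in every alternative. Gastric mucous genes had a median of 2.59 toward a weaker origin effect in KPten (adjusted p = 2.4e-09, and adjusted p = 0.034 with an estimated correlation), with 13 members not called on either scale. The list lost its call with fry, as did every list called in this comparison. Without acinar-derived KPten culture 1, 2 or 3 the count was 1, 0 and 0, and without ductal-derived KPten culture 1 or 2 it was 10 and 14.

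Between bulk tumours and complete-medium cultures of KTrp53, 49 genes differed in their origin effect, 36 higher and 13 lower, with 1615 at an unadjusted p under 0.05 and 127 by DESeq2. Digestive enzyme genes had 10 of 30 higher, 21 adjusted over the list alone (adjusted p = 1.2e-61, and adjusted p = 0.0041 with an estimated correlation), with Cpa2 at 7.41 ± 1.02 (adjusted p = 9.4e-05), Ctrl at 7.61 ± 1.08 (adjusted p = 9.4e-05) and Sycn at 10.84 ± 1.77 (adjusted p = 0.00060). In the fit of bulk tumours alone none of these enzyme genes was called by origin. The fit used here shares its dispersion between tumours and cultures, so its p-values do not measure the spread between tumours alone. Kras was higher by 1.68 ± 0.36 (adjusted p = 0.019), though in bulk tumours alone its origin difference was not called (1.29 ± 0.435, adjusted p = 0.30). Ductal-derived bulk tumours held 258 ± 153 CPM (SD, n = 5) against 105 ± 21.4 CPM (n = 4) with acinar origin, while cultures held 97.0 ± 20.4 (n = 14) and 126 ± 45.7 CPM (n = 19). Ductal-derived tumours 3 and 1 held 92.0 and 142 CPM, in or near the 88.6 to 136 CPM of the acinar-derived tumours. MAPK output genes had 9 of 22 higher and 1 lower adjusted over the list alone and 22 not called over all genes (adjusted p = 7.7e-06; adjusted p = 0.069 with an estimated correlation). Macrophage markers had 1 of 18 higher, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 3.1e-06; adjusted p = 0.14 with an estimated correlation), Lyz2 at 6.27 ± 1.40 (adjusted p = 0.028). Syt11 (-1.74 ± 0.41), Gas2 (-1.42 ± 0.33) and Nmnat3 (-1.32 ± 0.29) were lower. The count was 75 without acinar-derived bulk tumour 2, 24 without acinar-derived bulk tumour 4 and 30 without ductal-derived bulk tumour 3, and 6, 6 and 3 against cultures of batch A, B or C alone.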

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

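Tests for mislabelled libraries, for origin exchanged within batches and within Ddx3y classes, for the 2 sources of acinar enzyme RNA and for fibroblasts, and the test of origin against genotype in dropout medium, were chosen only after the results were seen. The library batch and single library tests had bounds written beforehand.

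Among 94 groups of bulk tumour values tested for a tumour far from the others, 10 were flagged, and chance flags about 1 in 20 groups. As log2 CPM, Sall1 lay at 2.73 in ductal-derived tumour 1 (3.80 to 4.17 in the others) and Lrig3 at 5.42 in acinar-derived tumour 1 (4.60 to 4.71). Acinar-derived tumour 4 was low in epithelial junction genes, with a mean of 4.44 (5.47 to 5.64), and acinar-derived tumour 1 in cell cycle genes, at 3.98 (5.51 to 5.72). Ductal-derived tumour 2 was low in FOXO targets, at 4.86 (5.42 to 5.65), and ductal-derived tumour 3 high in amino acid response genes, at 5.56 (4.72 to 4.91). Red blood cell genes were high in ductal-derived tumour 1, at 6.64 (2.28 to 3.48), and in acinar-derived tumour 4, at 8.71 (4.35 to 4.96). Sex-linked genes lay at -1.89 in ductal-derived tumour 1 (4.60 to 5.31) and at -1.36 in acinar-derived tumour 2 (4.44 to 5.07).

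Other results were flagged because an origin effect differed between genotypes or between tissue and culture in a test of that difference. In complete medium 6 genes differed between genotypes, among them Tpm3-rs7 (5.23) and Eno1b (9.93), in dropout medium 1767, and between tissue and culture 49. The last include Sycn (10.84), Amy2a2, Amy2a3 and Amy2a4 (8.84 each), Amy2a5 (8.58), Pnliprp2 (8.55), Kras (1.68), Syt11 (-1.74), Gas2 (-1.42), Nmnat3 (-1.32), Nadk2 (-1.18) and Ccdc18 (-1.12). The Amy2a copies share their reads and are uncertain.

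Lists with a different origin effect between genotypes in complete medium were gastric mucous genes and interferon genes (adjusted p = 2.4e-09 for each), classical PDAC genes (adjusted p = 2.9e-07), p53 targets (adjusted p = 2.1e-05), early stress genes (adjusted p = 5.0e-05), glucocorticoid targets and macrophage markers (adjusted p = 0.0054 for each), MAPK output genes (adjusted p = 0.0059), amino acid response genes (adjusted p = 0.0077), mitochondrial messenger RNAs (adjusted p = 0.010), and digestive enzyme and sex-linked genes (adjusted p = 0.018 for each). Only the gastric mucous list kept its call with an estimated correlation (adjusted p = 0.034), and none of these 12 lists kept its call with fry. Between tissue and culture they were digestive enzyme genes (adjusted p = 1.2e-61), islet markers (adjusted p = 4.0e-10), macrophage markers (adjusted p = 3.1e-06), MAPK output genes (adjusted p = 7.7e-06), p53 targets (adjusted p = 3.3e-05), early stress genes (adjusted p = 5.6e-05), epithelial junction genes (adjusted p = 0.00022), basal-like PDAC and red blood cell genes (adjusted p = 0.0065 for each), and cholesterol synthesis genes and B and plasma cell markers (adjusted p = 0.011 for each). Only the digestive enzyme list kept its call with an estimated correlation (adjusted p = 0.0041), in a fit that shares its dispersion between tumours and cultures.

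The first pattern weighed is the origin difference in complete-medium KTrp53 cultures. With library batch as a term 1229 genes were called, below the bound of 1551 written beforehand, a bound that was wrong because the fit of these 2 groups called 1432 even without batch. Batch as the whole cause is argued against by exchanges of origin within batches in the same fit: 1 of 40, the real one, reached 1229, and the highest other called 1. Ddx3y class, set by the sex of the animals or by loss of the Y chromosome in culture, moved with origin, and with it as a term 794 genes were called. Ddx3y class as the whole cause is argued against by exchanges within Ddx3y classes: 1 of 40, the real one, reached 794, and the highest other called 78. The sex of the animals was not measured otherwise, and a part played by it stays open, because the count fell from 1432 to 794, which the overlap of the term with origin would also bring. Sox9 lay inside the range of the other origin in 0 cultures. That was known when the test for mislabelled libraries was chosen, so it cannot decide on mislabelling. The En1 ranges did overlap, with 0.040 CPM in acinar-derived 16 and 0.055 CPM in ductal-derived 11. Origin itself stays open as the biological explanation, along with differences between the Ptf1aCreER and Sox9CreER alleles, which the design does not separate from origin.

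The second pattern is digestive enzyme RNA in ductal-derived bulk tumours. Of 30 measured enzyme and regulator genes, 27, Cpa1 itself included, had their highest and lowest ductal-derived tumour where Cpa1 had them (tumours 3 and 2). Random order would give 1.5, a value that does not allow for Cpa1 matching itself. That fits varying amounts of normal acinar tissue in the dissected pieces, but acinar genes regulated together in tumour cells would share an order as well. The test therefore cannot decide between the 2 sources. The cultures do not decide it either, because Cpa1 reached only 0.0422 CPM in cultured ductal-derived KTrp53 cells and culture may end such expression.

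The third pattern is the opposite origin effect on epithelial and mesenchymal genes in dropout medium. Without any 1 dropout library the correlation between the 2 origin effects was at most -0.0845, against -0.146 with all. That test covers all genes and cannot show what 1 library adds to these lists. The epithelial junction mean in log2 CPM was 5.01 and 1.70 in ductal-derived and 6.76 to 6.92 in acinar-derived KPten dropout cultures. It was 6.57 and 6.44 in ductal-derived and 3.74 and 4.24 in acinar-derived KTrp53 ones, so the opposite direction did not rest on 1 library for that list. Dcn, Lum and Thy1, named afterwards, were at most 0.0404 CPM in the ductal-derived KPten cultures, which argues only against fibroblasts that express these genes. The fixed list of fibroblast markers went the other way. It was higher there, also with an estimated correlation, and Pdgfrb lay at a mean of 209 CPM. Fibroblasts as a source therefore stay open. A genotype-dependent effect of origin stays open, as do differences between the few animals behind these 9 cultures.

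Splits of the libraries into arbitrary groups were compared with the real grouping, which counts as 1 of the splits. In bulk tumours 5 of 100 splits called as many genes as the real 1, the highest other calling 2, and for origin by genotype in complete medium 11 of 40 did (real 6, highest other 13), so neither count stands above chance. For origin in complete-medium KPten there were too few splits to tell (real 24, highest other 9). Only 1 of 40 splits, the real one, reached the count for origin in complete-medium KTrp53 (real 2327, highest other 515), genotype in complete (4701, 2002) and dropout medium (3325, 1873), medium in KTrp53 (3787, 54) and KPten (3316, 1108), tissue (11643, 5317) and origin by tissue (49, 27). For medium in KPten, where the numbers pair the acinar-derived cultures, 5 other splits parted as many pairs as the real one and called at most 1108, and 34 parted fewer and called at most 804. The 5 pairs counted include the 2 ductal-derived ones, for which the pairing did not meet the rule.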

How the results depend on the processing

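Of 2065 values of 119 named genes under the alternatives, 1736 kept direction and call, 323 kept direction and lost the call, and 6 changed direction. Of 131 called lists, 13 kept their call with an estimated correlation and 83 with fry, and 0 changed direction. Groups of 2 or 3 libraries, and genes near the floor at 17.1 M counts, limit what could be called, and where a group was left with 1 library it was assumed to vary like the others. RLE scaling, no robust estimation and keeping near-identical libraries apart moved no count by over 1.5 times. Leaving out libraries labelled with 1 floxed allele could not be done for comparisons with complete-medium acinar-derived KPten, where all 3 are so labelled, and leaving out 1 library at a time did not apply to origin in complete-medium KTrp53. Where nothing else is said, the cause was not tested.

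DESeq2 called 497 genes for bulk origin (1 as reported), 76 for origin in complete KPten (24), 818 in dropout KTrp53 (298), 38 for origin by genotype (6) and 127 for origin by tissue (49). The strict filter, with fewer genes tested, gave 13 for origin in complete KPten and 8 for origin by tissue, and no filter gave 187 for origin in dropout KTrp53. Protein-coding genes alone gave 9 for origin in complete KPten and 1 for origin by genotype. With all libraries in 1 fit, bulk origin gave 159. Fits of only the groups compared gave 1432 for origin in complete KTrp53, 84 in dropout KTrp53 and 6491 for medium in KPten. Without libraries labelled with 1 floxed allele, and so with fewer libraries, origin in dropout KPten gave 480 and genotype in dropout medium 1797.

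With Ddx3y class as a term, origin in complete KTrp53 gave 794, in a fit of 2 groups that gave 1432 without it. With batch as a term it gave 1229, and 77, 343 and 257 within the smaller batches A, B and C. Against complete KTrp53 libraries of batch A or B alone, genotype in complete medium gave 7267 and 7709 and medium in KTrp53 gave 6890 and 7168. With batch A, B or C alone, origin by genotype gave 2, 30 and 2 and origin by tissue 6, 6 and 3.

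Leaving out 1 library at a time, and so testing with fewer, gave 1 to 45 calls for bulk origin, 9 to 19 for origin in complete KPten, 11 to 160 in dropout KTrp53, 480 to 1853 in dropout KPten, 1797 to 3025 for genotype in dropout medium, 1583 to 2701 and 1466 to 2974 for medium in KTrp53 and KPten, 0 to 14 for origin by genotype, 24 to 75 for origin by tissue and 761 to 1822 for origin by genotype in dropout medium. It gave 3321 to 3697 for genotype in complete medium and 11268 to 11458 for tissue.

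With the replicate block, bulk origin gave 4, origin in complete KTrp53 736, complete KPten 9, dropout KTrp53 117 and dropout KPten 189, medium in KTrp53 121 and in KPten 5060, origin by genotype 3 and origin by tissue 12. Genotype in dropout medium gave 2237 with the block, against 3866 in the same fit without it. The block left counts for genotype in complete medium and for tissue within 1.5 times. For medium in KPten, where the acinar-derived pairing held but the block also joined the ductal-derived pairs, it changed only the call of the interferon list against the same fit without it. For pairings other than the acinar-derived KPten one, the correlations between same-numbered libraries ran from -0.276 to 0.428 (ductal-derived with acinar-derived complete KTrp53, the widest). Every library correlated best with its own number only in 2 pairs of ductal-derived KPten cultures between media and 2 of ductal-derived KPten with KTrp53 dropout cultures.

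Of the 6 values that changed direction, Acap1 for origin in complete KTrp53 (3.68) was -0.59 with the replicate block, -3.53 within batch A and -0.85 within batch B. Eno1b for genotype in complete medium (4.76) was -0.0622 without ductal-derived KPten culture 1 and at most 5.05 without another culture. Tpm3-rs7 for origin by genotype (5.23) was -0.0226 without ductal-derived KPten culture 3 and at most 5.80 without another culture. Rps12l1 for genotype in complete medium, at least 3106-fold lower with no count in 6 KPten libraries, was 0 against batch C alone.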

Other observations

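Beyond epithelial and mesenchymal genes, origin effects in dropout medium differed between KPten and KTrp53 in further gene groups. Duct markers had 12 of 22 lower and 1 higher in the KPten minus KTrp53 difference of origin effects (adjusted p = 2.3e-05; adjusted p = 0.12 with an estimated correlation), with Krt7 at -4.57 ± 0.86 (SE, adjusted p = 0.00030), and basal-like PDAC genes 5 of 24 lower and 1 higher (adjusted p = 0.00014; adjusted p = 0.069 with an estimated correlation). Fibroblast markers had 7 of 20 higher (adjusted p = 1.4e-05; adjusted p = 0.089 with an estimated correlation), glycolysis genes 3 of 26 higher (adjusted p = 0.0063; adjusted p = 0.63 with an estimated correlation) and cAMP and CREB targets 6 of 18 higher (adjusted p = 0.024; adjusted p = 0.48 with an estimated correlation). Among genes chosen after their values were seen, Sparc differed by 18.66 ± 3.48 (adjusted p = 0.00026), the intermediate filament gene Vim by 17.10 ± 4.03 (adjusted p = 0.0033) and Zeb1, a repressor of epithelial genes, by 11.78 ± 3.61 (adjusted p = 0.027). Epcam fell by 5.61 ± 1.09 (adjusted p = 0.00041) and the cadherin gene Cdh1 by 2.98 ± 0.72 (adjusted p = 0.0043). Sox9 differed by -0.41 ± 1.22 (adjusted p = 0.91), so its origin difference had no detected dependence on genotype.

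The higher Sox9 in every ductal-derived culture goes with the allele that drives the recombinase there. Whether the Sox9CreER construct adds Sox9 reads was not tested, because gene counts do not separate transgene from endogenous transcripts. In complete-medium KTrp53 cultures the leading components held 32.0% and 10.9% of the variance. The first went in part with batch: it was negative in every library of batches A and B, of either origin, and ran from -7.79 to 94.7 in batch C. Within batch C, ductal-derived 11 and 14 lay at -7.79 and -6.93 with Mki67 at 412 and 494 CPM. Ductal-derived 12 and 13 lay at 74.5 and 70.7 with 153 and 191 CPM, so batch and proliferation were not separated. The second component was negative in every ductal-derived library and ran from -10.2 to 53.5 in acinar-derived ones.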
